A study of Homo sapiens with 7 samples.

How the data were processed

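Blood samples of patients with a myeloproliferative neoplasm, enriched for CD34+ cells with magnetic beads, were profiled by single-cell RNA sequencing in 7 libraries. Per the labels' protocols, libraries followed a Drop-seq type of protocol in which each mRNA carries a cell barcode and a unique molecular identifier (UMI). The submitters' processing notes list CASAVA 1.8.2, bcl2fastq 2.19.0, STAR 2.5.2b, Seurat 2.3.0, R 3.4.1 and the genome build hg19. The role of each tool, the gene annotation, the cell filter and the use of strand are not given in the sources used here. The deposited values are UMI counts per gene and cell, whole numbers that were not normalized. Each file lists only genes with at least 1 UMI in its library, so an unlisted gene was read as 0. The annotation of hg19 was not used here, and no coordinates are given.

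Groups were taken from the sample titles, which give 3 libraries named ET, 3 named PV and 1 named MF. No label gives a fibrosis level for a sample, so none was compared. Each title was read as 1 patient and the library was the replicate. Genes on chromosome Y, XIST and TSIX were left out of every step.

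The gene symbols were found to differ in form between files. The files of ET3 and MF1 list SEPT15 in place of SEP15, which the other 5 files list, and ET3 lists 1-Dec, forms that a spreadsheet makes when it reads symbols as dates. SEPT15 was put back to SEP15 and 1-Dec to DEC1, and MARC1, MARC2, MARCH1 and MARCH2, which share a date form, were left out. This correction was made after a first round of results had been seen. Over whole libraries the edgeR counts did not differ between the corrected symbols and those as deposited, but the clusters did. With the symbols as deposited the largest named class was erythroid-like and edgeR called 2 genes within it; after the correction it was HSC/MPP-like and 0 were called.

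UMI counts were summed per library over all 6382 deposited cells. CPM (UMIs scaled to a common library total) of genes compared between groups use TMM library sizes fitted in that comparison, whereas CPM of CD34, JAK2 and CALR and of summed gene lists per library use total UMIs, so a gene given in both ways has slightly different values. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05), for PV against ET over 6 libraries and for MF against the mean of ET and PV over 7. MF has 1 library, so its spread was assumed to be that of the others. DESeq2 1.42.0 was an alternative. The 28 fixed gene lists with at least 3 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives. On simulated counts with 200 changed genes, the PV against ET test over 8513 genes recovered 81.2% of those changed by 2 on the log2 scale and 97.8% of those changed by 3. The MF test over 10558 genes recovered 32.7% and 61.9%. False calls numbered 6 and 5. Apart from the changed genes, every library was drawn around the same mean per gene, with a spread set by expression level alone. No simulated library differed from the rest over many genes at once, as ET3 does in the data. The recovered shares therefore need not hold for the data. In the simulation of a list raised by 1 on the log2 scale, camera recovered it in both comparisons. Genes were drawn independently there, so the simulation does not test camera on lists whose members are correlated. In the data the estimated correlation in PV against ET was 0.686 for the TNF and NF-kB response list and 0.754 for the monocyte markers. It was highest for the mature B markers, at 0.800.

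Cells with at least 200 detected genes (6350 of 6382) were clustered with scanpy 1.11.5 on 2000 variable genes, centred per library, with 20 principal components, 15 neighbours and Leiden resolution 1. A cluster was named after a cell class when at least 3 of that class's fixed markers were among its 30 leading genes, more than of any other class. The class also needed a marker among the first 10 of these genes, where no other class could have more. Doublets, called with scrublet in 95 cells (1.50%), were kept; the caller marked under 0.5% of cells in ET2, ET3 and MF1. Shares were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. The largest named class was also tested alone, in libraries with at least 20 of its cells.

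Genes named for PV against ET were the 12 higher and 12 lower with the smallest p among those past the threshold with groups that do not overlap, or the 6 with the smallest p in a direction with fewer than 6 passing. For MF they were chosen by fold change among genes outside the range of the other 6 libraries with at least 20 UMIs. Examples from a list without a passing member were taken from its 2 most expressed members, and CD34, JAK2 and CALR are given as levels. A pair of further genes picked by these rules are not reported here. Single HLA genes and clone names were left out, as was 1 gene picked for MF whose level can show an inherited deletion. The tests, lists, rules and most alternatives were fixed before the data were examined. The closing section names those added later. Alternatives covered scaling, filters, cells, doublets, depth, clustering, design and leaving out each library.

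Total UMI counts per library ran from 1727780 to 6142082. Intervals and limits from counts cover counting error only.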

Results

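Single-cell RNA sequencing was carried out on CD34+ cells, the fraction of blood cells that holds stem and progenitor cells, from patients with a myeloproliferative neoplasm. The design names fibrotic level as the subject of the study. The titles named 3 libraries ET, 3 PV and 1 MF. The files held 657, 762 and 1217 cells for ET1, ET2 and ET3, 943, 923 and 776 for PV1, PV2 and PV3, and 1104 for MF1. Total UMI counts were 1727780, 1934757 and 6142082 in ET, 3086821, 2785836 and 3508205 in PV, and 3746639 in MF1. CD34, the selection marker, was measured at 10.8 to 63.3 CPM of total UMIs, lowest in PV2 and highest in MF1. CALR, an endoplasmic reticulum chaperone, lay between 326 and 659 CPM, and JAK2, a cytokine receptor kinase, between 2.87 and 14.9 CPM.

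The first comparison asked how PV libraries differed from ET libraries. No gene passed the test. The smallest p values with groups that did not overlap belonged to GNG11, a G protein gamma subunit, at 2.01 ± 0.460 CPM in PV and 16.0 ± 3.15 CPM in ET (SD, n = 3 each), and to CDKN1C, a cell cycle inhibitor, at 0.656 ± 0.255 and 6.51 ± 2.79 CPM. In PV1, PV2 and PV3 GNG11 had 8, 4 and 8 UMIs and CDKN1C 2, 1 and 4, so both PV values rest on few counts. CDKN1C had 6, 13 and 51 UMIs in ET1, ET2 and ET3. GNG11 was also a leading gene of the megakaryocyte-like cluster, whose share was 0.114% ± 0.107 in PV and 0.464% ± 0.314 in ET. Among the ET libraries GNG11 did not follow that share. It was highest in ET2, at 19.6 CPM with 1 such cell, against 13.6 in ET1 with 5 and 14.8 in ET3 with 6. PV1 held 2 such cells and had 2.53 CPM. PADI4 had 5.98 ± 0.916 CPM in PV and 19.8 ± 6.96 in ET, and SLC12A5 and ACSL1 also had lower PV values. On the other side stood MT1E, a metallothionein, at 49.9 ± 21.4 CPM in PV and 14.2 ± 9.65 in ET, and LMNA, which encodes lamins A and C, at 291 ± 42.6 and 160 ± 29.3 CPM. C3orf14, RPUSD1, PRR5L and FRAT1 were the others with higher PV values.

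With edgeR's quasi-likelihood test 0 of 8831 genes passed, 383 had an unadjusted p under 0.05 (4.34%), and DESeq2 called 0 higher and 6 lower in PV, GNG11 among them. GNG11 had a log2 fold change of -2.96 (SE 0.40, edgeR adjusted p = 0.276). Groups did not overlap in 353 genes on the higher and 378 on the lower side, 8.28% of genes, where chance gives 10%.

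**Figure D1:**
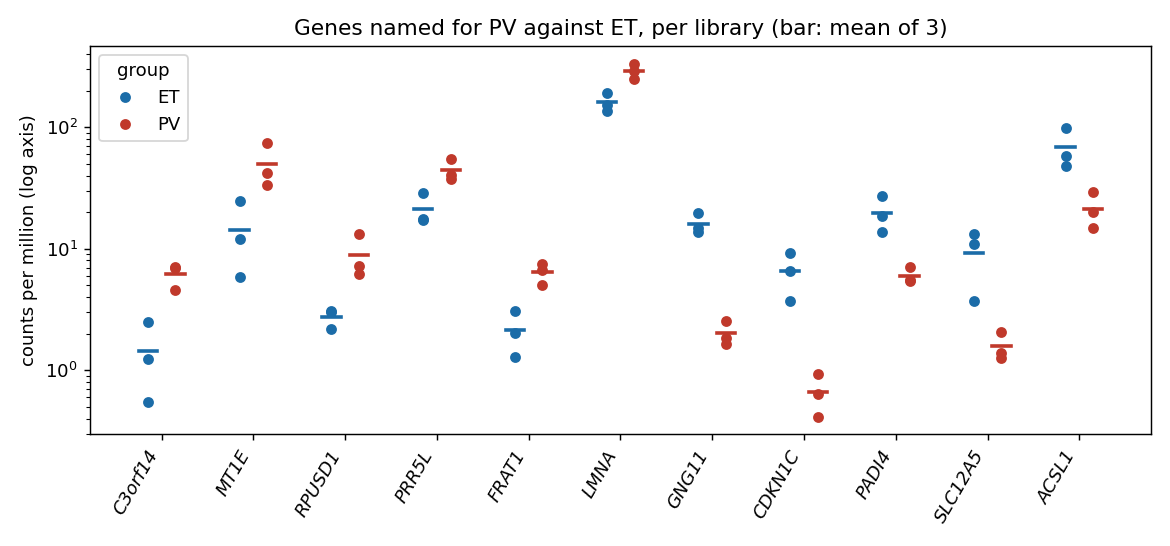
CPM of the 11 genes named for PV against ET, on a log axis, with a point per library and a bar at the mean of 3. The values of the groups do not overlap in any of them, as the rule that picked them requires, and none passed the test; GNG11 averaged 2.01 CPM in PV and 16.0 in ET.

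Among gene lists, 12 were lower and 5 higher in PV by camera, and no member of any passed over all genes. The TNF and NF-kB response list, which holds inflammatory cytokines, was lower with 23 of 23 members down (adjusted p = 6.4e-08; adjusted p = 0.507 with an estimated correlation). IL8, a neutrophil chemokine, had 4107 ± 1415 CPM in PV and 8649 ± 9525 in ET, and NFKBIA, an inhibitor of NF-kB, 908 ± 277 and 1571 ± 1029. The wide ET spread came from ET3, in which the summed level of the list was 40887 CPM, against 5662 to 13007 in the other ET and PV libraries. IL8 had 19641 CPM in ET3, 2839 and 3466 in ET1 and ET2, and 3102, 3494 and 5725 in PV1, PV2 and PV3, so without ET3 its PV mean was the higher. The summed level of the list turned likewise, at 5905 and 7948 CPM in ET1 and ET2 and 7108, 5662 and 13007 in PV. The mean log2 difference of the members from other genes was -1.68 in edgeR's fit of the 6 libraries and -1.28 in limma's voom fit of them, and voom gave -0.38 without ET3 (camera adjusted p = 0.0286). Mitochondrially encoded genes were lower with 26 of 26 members down (adjusted p = 5.5e-13; adjusted p = 0.480 with an estimated correlation). They took 1.58% of UMIs in PV3 and 4.86% to 6.96% in the other ET and PV libraries. The lower PV mean of their summed level rests on PV3, since PV1 and PV2, at 48556 and 69648 CPM, lay on either side of ET1, ET2 and ET3 (50857, 63285 and 64379 CPM). The list still passed by camera without PV3, with a smaller mean log2 difference from other genes. MT-RNR2, the large ribosomal RNA, which can share reads with nuclear copies, had 33844 ± 26090 CPM in PV and 42650 ± 7438 in ET.

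The immediate early list (14 of 17 members down), fibrosis-associated secreted factors (17 of 22), interferon response (20 of 27), heat shock (12 of 14), p53 targets (15 of 18), TGF-beta response (10 of 16), antigen presentation class II (10 of 11) and ribosomal proteins (47 of 76) were also lower, as were the HSC/MPP markers (8 of 10). The fibrosis-associated list, which shares IL8 with the TNF and NF-kB list, summed to 22918 CPM in ET3, 3459 and 4512 in ET1 and ET2, and 4033, 3537 and 8005 in PV, so without ET3 the PV mean of this sum was the higher. That list still passed by camera as lower without ET3, with a smaller mean log2 difference from other genes. The heat shock list summed to 11504, 10393 and 6054 CPM in ET1, ET2 and ET3 and 9353, 7800 and 12007 in PV1, PV2 and PV3. Its summed level thus overlapped between groups, lowest in ET3 and highest in PV3. Monocyte markers were lower with 5 of 5 members down and 4 passing adjusted over the list alone. LYZ, lysozyme, had 13.6 ± 8.15 CPM in PV and 211 ± 333 in ET, with 595 CPM in ET3, 6.81 and 30.6 in ET1 and ET2, and 7.45 to 22.8 in PV. The ET mean rests on ET3, and the list still passed by camera without ET3, with a smaller mean log2 difference from other genes. Higher lists were the unfolded protein response (18 of 21 members up), S phase (14 of 17), haem synthesis and iron (11 of 14), hypoxia and glycolysis (14 of 19) and erythroid markers (10 of 10). ENO1, a glycolytic enzyme, had 470 ± 84.8 CPM in PV and 302 ± 45.2 in ET, and FTL, ferritin light chain, 7594 ± 1495 and 5260 ± 2578. For these 15 lists camera's adjusted p was at most 0.0341 with the preset correlation, and the smallest adjusted p over all lists was 0.480 with an estimated correlation. Adjusted over the list alone, no list but the monocyte markers had a passing member. In CPM, the unfolded protein list summed to 2523, 2516 and 2135 in ET1 to ET3 and 3088, 2248 and 4242 in PV1 to PV3. The immediate early list summed to 1125, 969 and 1665 CPM in ET and 694, 892 and 1033 in PV, in the same order. Both thus overlapped between groups, with PV2 below ET1 and ET2 in the first and PV3 above ET2 in the second. The TNF and NF-kB, immediate early, fibrosis-associated and unfolded protein lists passed in every alternative except the estimated correlation and fry. So did the mitochondrially encoded list where it was tested, since the alternative without mitochondrial genes leaves it no members. Each of the other 12 lost its call in at least 1 further alternative: without ET3 the S phase, interferon, TGF-beta, haem and iron, class II and HSC/MPP lists no longer passed, with S phase and interferon turning direction, and without PV3 the S phase, interferon, TGF-beta, p53, class II, HSC/MPP and erythroid lists no longer passed and the ribosomal proteins turned direction. G2M phase, JAK-STAT targets, oxidative phosphorylation, class I, adhesion and homing, and the megakaryocyte, granulocyte-monocyte progenitor, dendritic, eosinophil-basophil-mast, lymphoid and mature B markers did not pass.

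**Figure D2:**
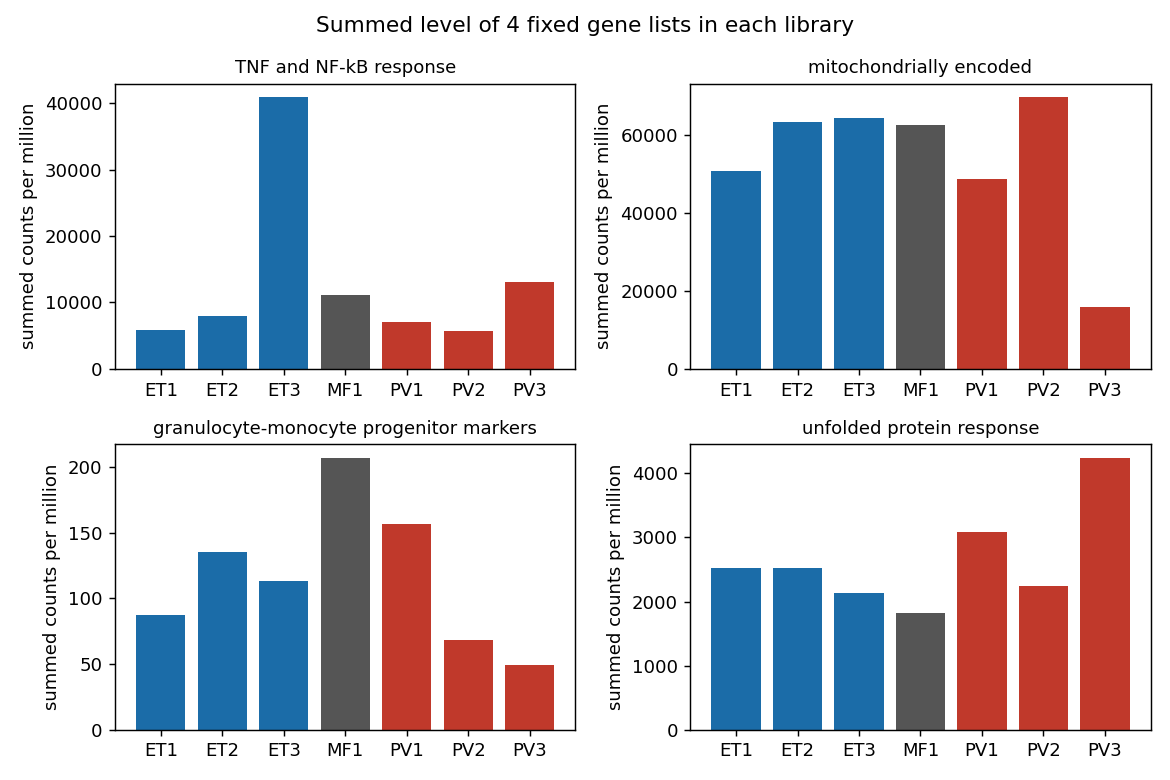
Summed CPM of 4 fixed gene lists in each of the 7 libraries (ET blue, PV red, MF grey), with axes from 0. The TNF and NF-kB response list stood at 40887 in ET3, and mitochondrially encoded genes at 15827 in PV3.

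Cells fell into 18 clusters, of which 6 were each named after a class, and 4068 of 6350 cells stayed unnamed. HSC/MPP-like cells, named in this clustering and in none of the alternative clusterings, were led by AVP, HOXA9 and SPINK2. They made up 21.7% ± 5.13 of PV cells and 10.9% ± 9.49 of ET cells (SD, n = 3 each, exact permutation p = 0.2). They numbered 94 of 656 cells in ET1, 134 of 737 in ET2 and 2 of 1214 in ET3, and the difference was 10.8 percentage points with ET3 and 5.44 without it. The share ran opposite to the HSC/MPP marker list, whose summed level was highest in ET3 at 693.9 CPM. SPINK2 had 272 CPM in cluster 17, an unnamed cluster of ET3 cells, and 193 CPM in the HSC/MPP-like cluster, whereas AVP had 47.2 and 60.6 CPM. Other unnamed clusters also exceeded the HSC/MPP-like cluster. AVP had 97.7 CPM in cluster 2, 65.4 in cluster 0 and 62.3 in cluster 8, and SPINK2 363 in cluster 6 and 241 in cluster 8. Eosinophil-basophil-mast-like cells, led by HDC, GATA1 and CPA3 and by the metallothioneins MT1E and MT2A, were at 17.1% ± 6.44 and 11.4% ± 9.33 (exact permutation p = 0.6), with a difference of 0.309 percentage points without ET3. Monocyte-like cells, led by S100A9, S100A8 and CCL3, were at 0.0859% ± 0.149 in PV and 6.53% ± 10.5 in ET. They were the only 1 of the 6 named classes whose shares did not overlap (exact permutation p = 0.1, the smallest this design can give), and 226 of the 243 cells came from ET3, without which the difference was -0.406 percentage points. The gap between the groups rests on 2 of 656 cells in ET1 against 2 of 776 in PV3. Mature B-like cells were at 4.23% ± 5.53 and 3.18% ± 2.58 (p = 0.8, exact), erythroid-like cells at 3.26% ± 5.11 and 0.283% ± 0.272 (p = 0.5, exact), and megakaryocyte-like cells at 0.114% ± 0.107 and 0.464% ± 0.314 (p = 0.2, exact). PV3 held 71 of the 84 erythroid-like cells, and that difference was 2.98 percentage points with PV3 and 0.0356 without it. The erythroid-like shares depended on the clustering and were larger in both groups in all 6 alternative clusterings. Their means were 16.8% in PV and 11.3% in ET at Leiden resolution 0.5, 8.32% and 3.81% at 1.5, and 18.1% and 10.3% with no centring. The exact permutation p was 0.4 to 0.6 over the 6. Their differences were 1.20 to 10.45 percentage points without PV3 and -0.457 to 2.85 without ET3. PV2 held 98 of the 205 mature B-like cells, whose difference was -2.14 percentage points without PV2 and -0.287 without ET3. Clusters 16 and 17, with 109 and 786 cells, held ET3 cells only.

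Within the HSC/MPP-like cells, the largest named class, 0 of 4650 genes passed edgeR's test between PV1, PV2 and PV3 and ET1 and ET2, with 152 at an unadjusted p under 0.05 and 0 by DESeq2. ET3 had 2 such cells and was not used. The genes with the smallest p on each side were FUBP1, with a log2 fold change of 1.92 (SE 0.48, edgeR adjusted p = 0.980), and RPL17 with -2.21 (SE 0.50, adjusted p = 0.980). RPL17 has many processed pseudogenes, so its count is uncertain. The class depended on the clustering: in each of the 6 alternative clusterings, examined after the data were seen, no cluster was named HSC/MPP. Another class was the largest (erythroid-like in 5, eosinophil-basophil-mast-like in 1), and 1 to 4 genes passed in it. The 6 clusterings regroup the same cells, so calls in them are not separate tests. CXCL10, an interferon-induced chemokine singled out after its values were seen, was higher in PV in all 6, none of which used ET3 (adjusted p from 0.00614 to 0.0483). Its log2 fold change was 3.98 (SE 0.67, edgeR adjusted p = 0.0115) in the erythroid-like class found with the symbols as deposited, where it had 98, 34 and 59 UMIs in PV1, PV2 and PV3 and 2 each in ET1 and ET2, and 1.74 (SE 0.63, adjusted p = 0.998) in the HSC/MPP-like cells.

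The next comparison set the MF library against the mean of ET and PV. With 1 MF library, the test assumes that it varies like the others. OSTM1-AS1, an antisense transcript, had 186 UMIs in MF1 and 1 in the other 6 libraries together, all in PV1, and was the only gene that passed (edgeR adjusted p = 0.0141). Its reads cannot be told from those of its partner gene without strand. C22orf43 (75 UMIs in MF1, 1 in PV3), SNHG18, AZU1 and MAMDC2 also lay above the range of the others without passing. AZU1, a granule protein of granulocyte precursors, had 7.67 CPM in MF1 and at most 1.62 CPM elsewhere. Below the range lay TPSAB1, a mast cell tryptase with a near-identical paralogue, and MT1G, a metallothionein, each with 0 UMIs in MF1. TPSAB1 had 0.940 to 64.8 CPM and MT1G 5.02 to 35.8 CPM in the others. CALB2, TKTL1, VGF and IGJ were lower too without passing.

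Of 11095 genes, edgeR called 1 higher and 0 lower in MF, 1029 had an unadjusted p under 0.05 (9.27%), and DESeq2 called 8 higher and 31 lower. MF1 lay above the other 6 libraries in 2113 genes and below them in 2028, 37.3% of genes, where chance gives 28.6%. OSTM1-AS1 no longer passed, leaving 0 calls, without PV1, PV2 or PV3, in cells with at least 500 genes, or when thinned to the smallest library. Without ET3 the count became 203 higher and 89 lower. ET3 and MF1 were the 2 files with date-converted gene symbols, and with a term for those files 0 genes passed. MF has only MF1, so that term was fitted from ET3 against ET1 and ET2 alone. It takes up every trait of ET3, so the 0 calls cannot speak to file handling. In the 292 genes called without ET3, ET3 lay on the same side of the other 5 libraries as MF1 in 96.2%. Without ET3, MF1 was the only library with converted symbols, so MF and that property coincide in these calls.

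**Figure D3:**
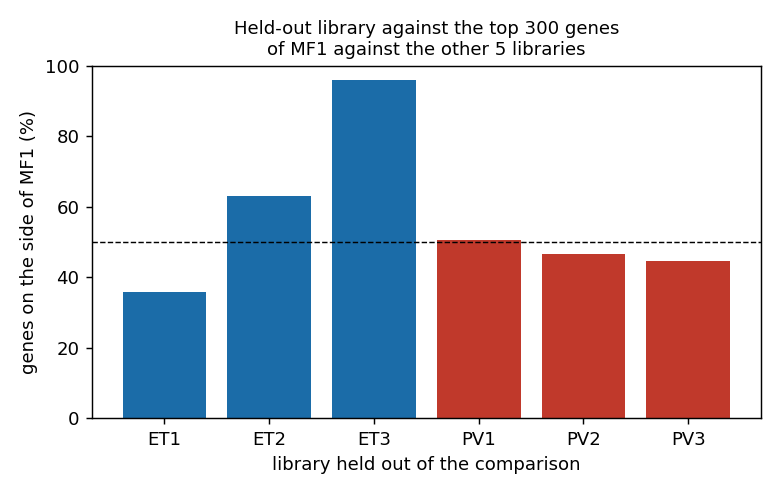
For each ET and PV library held out, MF1 was compared with the other 5, and the bar (ET blue, PV red) gives the share (%) of the 300 genes with the smallest p in which the held-out library lay on the side of MF1; the dashed line marks 50%. ET3 stood at 96.0%, the others between 35.7% and 63.0%.

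By camera, 4 lists were higher and 2 lower in MF. G2M phase genes were higher with 15 of 17 members up and 3 passing adjusted over the list alone (adjusted p = 4.6e-06; adjusted p = 0.546 with an estimated correlation). HMGB2, a chromatin protein, had 231 CPM in MF1 and 42.5 to 148 CPM elsewhere, whereas TUBB4B, a tubulin, had 71.7 CPM against 72.0 to 300 CPM. MKI67, a proliferation marker named after its value was seen, had 43 UMIs in MF1 and at most 5 in any other library. Granulocyte-monocyte progenitor markers were higher with 8 of 11 members up and 3 passing adjusted over the list alone (adjusted p = 6.1e-05; adjusted p = 0.697 with an estimated correlation). PRSS57 had 79.7 CPM in MF1 and 29.8 to 106 elsewhere, and CSTA 2.72 CPM in MF1 and up to 47.5. MPO, myeloperoxidase, also named after its value was seen, had 42.8 CPM against at most 6.49.

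Mitochondrially encoded genes were higher by camera (26 of 32 members up, 2 passing adjusted over the list alone). Their mean log2 fold change was 1.19 and their median 0.617, so the members rose unequally. MT-TV, a mitochondrial transfer RNA named after its value was seen, had 15749 UMIs in MF1. It had 21 to 310 UMIs in ET1, ET2 and the PV libraries. The summed level of the list in MF1, 62647 CPM, lay inside the range of the others, below ET2, ET3 and PV2 (63285, 64379 and 69648 CPM), while PV3 had 15827 CPM. Antigen presentation class I was also higher (10 of 11), in which B2M, the light chain of class I molecules, had 3174 CPM in MF1 and 1676 to 3379 elsewhere. Both had adjusted p = 0.851 with an estimated correlation. The unfolded protein response was lower with 19 of 21 members down (adjusted p = 0.000179; adjusted p = 0.546 with an estimated correlation). CALR had 302 CPM in MF1 and 376 to 685 elsewhere, and HSP90B1, another chaperone of the endoplasmic reticulum, 228 against 335 to 549. Heat shock genes were lower with 10 of 14 members down (adjusted p = 0.0193; adjusted p = 0.752 with an estimated correlation), with HSP90AA1 at 2054 CPM against 2205 to 5288. With a term for the files with converted symbols, which rests on ET3, class I turned direction and heat shock no longer passed. The G2M, progenitor and unfolded protein lists passed in every alternative except the estimated correlation and fry. So did the mitochondrially encoded list where it was tested, since the alternative without mitochondrial genes leaves it no members. The other 22 lists did not pass.

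Of 1101 clustered MF1 cells, 14.2% were HSC/MPP-like (exact binomial 95% interval 12.2 to 16.4) and 6.54% eosinophil-basophil-mast-like (5.15 to 8.16). Cluster 6, led by MPO and ELANE and left unnamed, held 40 MF1 cells of 52, and cluster 7, led by the S phase genes CLSPN, TYMS and PCNA, 51 of 99. Cluster 8 held 296 MF1 cells of 423. With 1 MF library no test of these shares was made, and a cluster mostly of 1 library may be that library and not a cell type.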

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

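Alternatives that leave out monocyte-like and B-like cells, keep symbols as deposited, add a term for files with converted symbols, or move the within-class test to another clustering were chosen after seeing the data. For PV against ET, 0 genes passed under most settings and in all fits that left out 1 library (0 to 0). DESeq2 called 6, all lower, and the test with no filter, which adds genes with few counts, 299 (17 higher, 282 lower). Same-numbered libraries had correlations of deviations of 0.0158, -0.0407 and 0.149, and the other ET and PV pairs -0.144 to 0.181. No pairing by number was seen, though so few values cannot exclude it. The replicate block called 4 genes and 16 lists. For MF the count was 39 with DESeq2, 236 with no filter, 0 in cells with at least 500 genes, 0 when thinned, 0 with a term for files with converted symbols, and 0 to 292 when 1 library was left out. The count of 292 came without ET3. Symbols as deposited gave 0 genes for PV against ET and 1 for MF.

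Called lists numbered 12 to 16 for PV against ET and 6 to 9 for MF when 1 library was left out. They numbered 0 in both comparisons with an estimated correlation and with fry, and 13 for MF with the term for converted files. Direction reversed, as mean log2 difference from other genes in voom fits, for S phase (-0.28 with that term, -0.21 to 1.09 without 1 library, lowest without ET3), interferon response (0.11 with that term, -0.81 to 0.10 without 1 library, highest without ET3), ribosomal proteins (-0.34 to 0.12 without 1 library, highest without PV3) and, for MF, class I (-0.29 with that term). For PV against ET, that term takes ET3 out of the ET mean, so it is no separate check from the fit without ET3. For MF it is fitted from ET3 against ET1 and ET2 alone, so it cannot tell file handling from other traits of ET3. The cause was not tested.

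Within the largest class the count was 19 with no filter and 0 to 3 without 1 library, 3 without ET1, which leaves ET2 alone, assumed to vary like PV. It was 4 at Leiden resolution 0.5, 1 at 1.5, 1 with no centring, 2 without doublets, 2 with symbols as deposited and 3 in cells with at least 500 genes, where the largest class was another. Non-overlapping classes numbered 2 with no centring and 1 to 3 without 1 library. Pseudocount alternatives did not apply to counts, and the within-class fit without ET3 was not run because ET3 was not in it. Depth limits genes such as SNHG18, with at most 2 UMIs in each library but MF1.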

Other observations

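The tests of genes and lists by split, of the IL8 to S100A8 ratio, of MF1 in the TNF and NF-kB list, of ET3 in the progenitor and G2M lists and of those lists after thinning were chosen after the result was seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 genes, as did all 10 splits (highest other 0), and 17 lists, where the highest other split called 13 and 1 split, the real one, called as many as 17.

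The first pattern is the high TNF and NF-kB response level of ET3, 3.14 times the highest of the other 5 ET and PV libraries. Without monocyte-like and B-like cells the ratio was still 2.05, which argues against those cells as the whole source. IL8 to S100A8 UMIs stood at 12.8 inside the monocyte-like cells and 513 outside, 40.1 times higher. Other cells held IL8 in every library (9810 UMIs in PV1, with 0 monocyte-like cells), so a higher ratio outside alone decides nothing. In ET3, S100A8 fell from 2606 CPM inside to 27.3 outside. IL8 fell from 33300 to 14003, against 2576 to 6951 outside in the other libraries. This argues against free RNA as the whole source of IL8. CCL3 (15132 and 156 CPM) and IL1B (13716 and 193) fell more like S100A8, so free RNA stays open for them. MF1, whose file has the same symbol conversion, was at 0.861 of the highest of the other 5, PV3, and above the other 4, so file handling shared with MF1 stays open. Sample handling and the donor were not tested.

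The second pattern is the level of granulocyte-monocyte progenitor and G2M genes in MF1, 1.32 and 1.09 times the highest of the other 6 libraries in summed CPM. After thinning to the smallest library both lists still passed by camera (the higher adjusted p was 0.0159), which argues against depth as the whole cause of the calls; the lower ratio was 1.10, but thinning does not move an expected CPM, so that ratio decides nothing. ET3 was at most at 0.724 of the highest of the other 5, and 1 library leaves open what the 2 files share. MF and the donor of its library cannot be told apart with 1 library.

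The third pattern is the rise from 1 to 292 calls for MF without ET3. ET3 lay on the side of MF1 in 96.2% of those genes, against 35.7% to 63.0% for the top 300 genes of each other library held out. The files of ET3 and MF1 alone list SEPT15, and 453 genes are listed in both and in no other file, where the next pair shares 207; both are deep libraries, which adds to such counts. A candidate explanation is that ET3 and MF1 were prepared or processed apart from the other 5, and the calls may then come from that and not from MF.

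CXCL10 passed in the largest class under all 6 alternative clusterings, none of which used ET3. These regroup the same cells, with 34 CXCL10 UMIs from PV2 in each, so they are not separate findings. Where that class was erythroid-like it held 696 to 839 cells, against 84 erythroid-like cells in the main clustering. Eosinophil-basophil-mast markers were also among its leading genes. With symbols as deposited 2 genes passed, CXCL10 and CCL2. CCL2, a monocyte chemoattractant, had a log2 fold change of -2.82 (SE 0.39, edgeR adjusted p = 0.00117) there. It passed in 4 of the 6 alternative clusterings. It did not pass at Leiden resolution 1.5 (-1.51, adjusted p = 0.997), with no centring (-1.98, adjusted p = 0.0589) or in the HSC/MPP-like cells (0.06, adjusted p = 0.998). In sums over all cells CXCL10 had a log2 fold change of -0.87 (SE 0.79, edgeR adjusted p = 0.974). Those sums include ET3, and CXCL10 had a positive log2 fold change in the HSC/MPP-like cells too (1.74, SE 0.63, edgeR adjusted p = 0.998), so the values do not point to a cell class. In the clustering without doublets CXCL10 was itself a leading gene of a cluster in the class, so the class and the gene are not independent there, and no other samples were tested.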
